A study of Homo sapiens with 4 samples.

How the data were processed

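Total RNA of HCT116 cells was labelled with biotin and hybridised to Affymetrix whole-transcript arrays, 1 array per sample, per the labels' protocols. The deposited values are log2 expression levels per transcript cluster, and per the submitters' processing notes the authors made them with Affymetrix Expression Console and RMA (background correction, normalization between arrays and summary of a cluster's probes). The versions, the RMA variant and the genome build are not given in the sources used here. The table held 67528 transcript clusters on each of 4 arrays, written with 2 decimals. Array medians lay between 4.58 and 4.66 log2 units, so genes had not been centred. Levels ran up to 19.93 on 3 arrays and up to 19.79 on control replicate 2, and between 6 and 9 clusters per array shared that top value. No tested gene lay at it. Between 267 and 284 clusters per array lay above 16 log2 units, so the scale reaches beyond what a plain log2 of a 16-bit scanner reading would give, and fold changes are stated on the deposited scale. Whether the processing widened them is not known. Scanner files and detection calls were not used here, so no probe was called present or absent.

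Samples were grouped by the treatment in their labels, 2 with control siRNA and 2 with CTNNB1 siRNA. The labels call them biological replicates and do not say that a replicate number marks a shared culture or day, nor whether replicates were separate cultures. The p-values of single genes in limma measure only the spread between these samples. Those of camera at its preset correlation, of Fisher's exact test and of the permutation of list members take genes as units. They do not measure how far further samples would vary. Gene names came from the platform's annotation table, which named 25324 clusters. Of these, 23781 carried 1 gene symbol and 1543 several, and 42204 clusters had no name in that table. Symbols were updated through the RefSeq gene table of assembly GRCh38.p14, by gene ID for 21497 clusters, by symbol for 1974 and by an unambiguous synonym for 306, and 4 names were kept as given. No coordinates are printed, because the build behind the clusters is not given. Where a gene had several clusters (528 genes), the cluster with the highest mean over the 4 arrays stood for it, which left 22411 genes. Of 188 further clusters of called genes, 144 were called in the same direction and 0 in the opposite one.

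Genes with a mean over all 4 arrays above the 30th percentile, which lay at 4.29 log2 units, were tested, 15679 in all. The deposited log2 values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with 2 groups, no block and no trend). The 2 residual degrees of freedom became 5.66 after moderation. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, with a threshold of 0.05. Levels are given as mean ± SD (n = 2), changes as log2 fold change of CTNNB1 siRNA over control siRNA with limma's moderated standard error (SE). Intervals are 95% intervals from the moderated distribution. All tests were 2-sided unless stated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

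Gene lists were fixed from textbook knowledge, 22 in all, together with the tests, the alternatives and the rule for named genes, before the data were examined. The 20 lists with at least 8 tested members were tested with camera (limma), which compares a list's shift with that of all other tested genes, at a preset correlation between genes of 0.01. The adjusted p then covers the 20 lists. Of these, 12 passed, 6 up and 6 down. With the correlation estimated from the 2 residual degrees of freedom none passed, and 1 list, that of histone genes, had an unadjusted p under 0.05. Correlation between members does not account for all of this loss. For YAP/TAZ targets the estimate was 0.0076, under the preset 0.01, yet the unadjusted p in camera went from 0.0014 to 0.082. For histone genes the estimate was -0.053, and the unadjusted p in camera went from 6.01e-07 to 0.032. By fry, which tests whether a list's own genes move on balance one way without comparing them with other genes, 10 lists passed. Of the list members, 86 had no cluster with 1 symbol and were not analysed here. The text names CTNNB1, the 12 protein-coding genes with the largest rise and, besides CTNNB1, the 12 with the largest fall among called genes whose groups did not overlap, and up to 4 members per list with the largest change (10 for Wnt targets, plus 10 Wnt targets fixed by name). Any other gene named was chosen after its values were seen, as stated there.

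The fit was tested on simulated data with the real genes' levels and moderated spreads, 15679 in all. The fit recovered 94.0% of 67 genes changed 1.5-fold, 100% of 67 changed 2-fold and 100% of 66 changed 4-fold, and 8.0% of its calls were unchanged genes. For lists, 1 list shifted by -0.5 was found and 0 of the others passed. The simulated genes varied independently, while the correlations estimated for the real lists ran from -0.09 to 0.79. The simulation therefore could not show how camera performs on lists whose members move together. Alternatives were the replicate number as a block, each array left out, eBayes with trend and robust settings, another quantile normalization, median centring, no level filter, the 50th percentile as the filter, the mean of a gene's clusters, each cluster tested on its own, an adjusted p under 0.10, fold limits of 1.5 and 2, and camera with an estimated correlation, on ranks, or replaced by fry.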

Results

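Gene expression was profiled in HCT116 cells, an established human colon cancer cell line that carries an activating mutation of its own beta-catenin gene and a wild-type p53. The question, as far as the labels state it, was how the transcriptome changes when CTNNB1, the gene for beta-catenin, is silenced. Beta-catenin is the transcriptional co-activator of the Wnt pathway and a structural component of adherens junctions. Cells received 50 nM of either a control siRNA or a CTNNB1 siRNA and were collected after 48 h. Each group had 2 biological replicates, and each replicate was hybridised to 1 array, which gave 4 arrays in all. Replicate arrays correlated across the tested genes with r = 0.997 in both groups, and arrays of different groups with r between 0.977 and 0.980. Genes are not independent replicates, so these coefficients only describe similarity. The number of arrays, and not a read depth, limits the precision of every value below.

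CTNNB1 itself, on chromosome 3, was measured by 1 transcript cluster, TC03000214.hg.1, and was lower in both arrays of the CTNNB1 siRNA group. Its level was 10.13 ± 0.10 log2 units with control siRNA and 6.58 ± 0.11 with CTNNB1 siRNA (mean ± SD, n = 2 each). It fell by 3.56 on the log2 scale (SE 0.10, 95% interval -3.79 to -3.32), which is an 11.8-fold difference on the deposited scale, with an adjusted p of 0.00013 in limma after Benjamini-Hochberg adjustment. The RMA variant behind the deposited scale is not given in the sources used here, so this and every other fold or log2 change could be larger than on a plain log2 intensity scale. Both arrays labelled CTNNB1 siRNA thus lay below both control arrays for the targeted gene. With any 1 array left out, the log2 fold change lay between -3.63 and -3.48, and its adjusted p in limma lay between 0.054 and 0.076, with 1 residual degree of freedom left.

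Silencing of CTNNB1 went with changes in a large part of the transcriptome. Of 15679 genes tested, 4756 passed the threshold of an adjusted p under 0.05, which is 30.3%. Of these, 2225 were higher and 2531 lower after CTNNB1 siRNA. The changes were mostly modest, with a median size of 0.60 log2 units among the called genes. A fold of at least 1.5 was reached by 1168 of the higher and 1287 of the lower genes, and a fold of at least 2 by 451 and 443. The values of the 2 groups did not overlap for 63.0% of the tested genes, where chance gives 33.3%. The design of 2 against 2 samples cannot go below p = 0.33 in an exact 2-sided permutation test of a single gene, so the test rests on limma's pooling of the spread across genes. No gene passed limma's adjusted threshold once any 1 of the 4 arrays was left out, although between 4739 and 4939 genes then had an unadjusted p under 0.05.

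**Figure D1:**
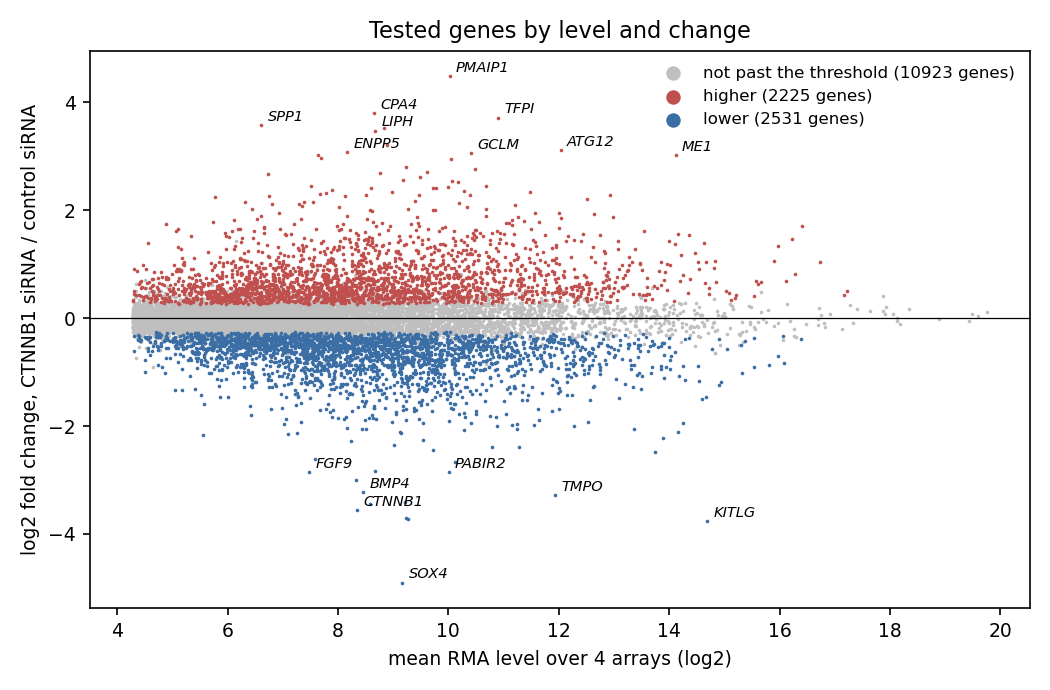
Each point is 1 of the 15679 tested genes, placed by its mean RMA level over the 4 arrays (horizontal axis, log2) and its log2 fold change after CTNNB1 siRNA (vertical axis). Red points are the 2225 genes called higher and blue points the 2531 called lower, and gene names mark CTNNB1 and those of the 24 named genes with room for a label.

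Among called protein-coding genes whose groups did not overlap, and besides CTNNB1 itself, the largest falls were led by SOX4, a transcription factor of progenitor cells. SOX4 dropped from 11.62 ± 0.03 to 6.72 ± 0.03 log2 units (mean ± SD, n = 2 each), a 29.9-fold difference on the deposited scale. It was followed by KITLG, the ligand of the KIT receptor, which fell by 3.76 on the log2 scale (SE 0.27). JAG1, a Notch ligand, fell by 3.73 (SE 0.18). RNF43, a ubiquitin ligase that removes Wnt receptors from the cell surface, fell by 3.71 (SE 0.13). The secreted factor BMP4 fell by 3.22 (SE 0.10) and FGF9 fell by 2.86 (SE 0.10). DUSP6, a phosphatase that inactivates ERK, fell by 3.41 (SE 0.22), and the immediate early transcription factors EGR1 and NR4A2 fell by 2.84 (SE 0.12) and 3.01 (SE 0.14). The remaining 3 of the 12 largest falls besides that of CTNNB1 were those of the metalloprotease gene ADAM19, of TMPO, which encodes lamina-associated polypeptides of the nuclear envelope, and of PABIR2. The adjusted p-values of these 12 genes in limma ranged from 4.02e-05 for SOX4 to 0.00073 for KITLG.

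The largest rise among called protein-coding genes whose groups did not overlap was that of PMAIP1, which encodes the pro-apoptotic BH3-only protein NOXA. It went from 7.79 ± 0.05 to 12.27 ± 0.23 log2 units (mean ± SD, n = 2 each), a 22.4-fold difference on the deposited scale with an adjusted p of 0.00013 in limma. CPA4, a carboxypeptidase gene, rose by 3.80 log2 units (SE 0.12), and TFPI, the inhibitor of the tissue factor pathway of coagulation, rose by 3.72 (SE 0.10). SPP1, which encodes osteopontin, rose by 3.58 log2 units (SE 0.09) from a low control level of 4.83. LIPH, a phospholipase gene, rose by 3.48 (SE 0.11), and GPAT3, an acyltransferase of triglyceride synthesis, by 3.20 (SE 0.09). The fatty acid hydroxylase gene CYP4F11 rose by 3.53 (SE 0.17). GCLM, the regulatory subunit of the first enzyme of glutathione synthesis, rose by 3.06 (SE 0.10), and ME1, the cytosolic malic enzyme that makes NADPH, by 3.02 (SE 0.10). The others were ATG12, an autophagy conjugation gene, ENPP5, and DPP4, a brush border peptidase, with rises between 3.02 and 3.12 log2 units.

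Wnt/beta-catenin target genes were lower as a group. Of 34 tested members of the fixed list of 50 genes, 19 fell, 2 rose and 13 did not pass the threshold. Adjusted over the list alone, 21 fell and 4 rose. The median log2 fold change was -0.51, with an adjusted p of 3.42e-06 in camera over 20 lists, and an adjusted p = 0.46 with an estimated correlation. Without a level filter the median was -0.145, and among genes above the 50th percentile it was -0.79. AXIN2, a scaffold of the destruction complex and a classical feedback target of the pathway, went from 6.64 ± 0.01 to 4.48 ± 0.01 log2 units (mean ± SD, n = 2 each). SOX9 fell by 1.53 (SE 0.30), CDCA7 fell by 1.42 (SE 0.12) and CEMIP fell by 1.33 (SE 0.09). With CTNNB1 siRNA, AXIN2 and CEMIP (4.51) lay near the level filter of 4.29, which limits how far their falls can be measured. CCND1, which encodes cyclin D1, fell by 1.03 (SE 0.11), MYC by 0.79 (SE 0.10) and ZNRF3, the paralog of RNF43, by 0.80 (SE 0.10). NKD1, an inhibitor of Dishevelled, had a log2 fold change of -0.30 (SE 0.10) and did not pass, with an adjusted p of 0.084 in limma. The NKD1 log2 fold change was -0.18 without control replicate 2. The 2 members that rose, named after their values were seen, were FOSL1, an AP-1 subunit, at 1.18 (SE 0.08) and the drug transporter gene ABCB1 at 0.63 (SE 0.11). LGR5, ASCL2, SP5 and LEF1 lay below the level filter of 4.29 log2 units in both groups and were not tested. Their group means were between 3.18 and 4.27.

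**Figure D2:**
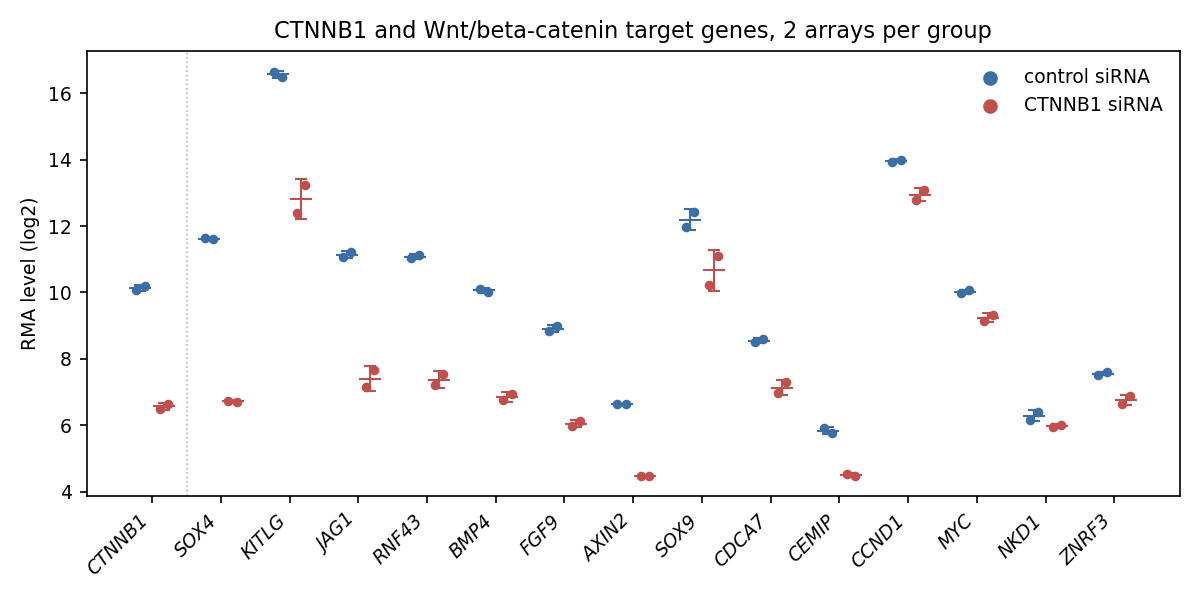
RMA levels (log2) of CTNNB1 and of 14 Wnt/beta-catenin target genes in each of the 2 arrays per group. Points are single arrays, horizontal bars are group means and error bars are SD (n = 2), and the groups do not overlap in any of these genes, although NKD1 did not pass the test.

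Components of the Wnt pathway that are not counted as targets did not pass the list test. Of 47 tested genes, 12 fell, 6 rose and 29 did not pass (7 rose and 12 fell adjusted over the list alone). The median was -0.07 log2 units and the adjusted p in camera was 0.36. BCL9, a beta-catenin co-activator, fell by 1.30 (SE 0.15), and WLS, which carries Wnt ligands to the cell surface, fell by 1.24 (SE 0.13). The receptor genes FZD3 and LRP6 had log2 fold changes of -0.92 (SE 0.11) and -0.87 (SE 0.11).

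The list of adherens junction and catenin family genes, which also holds desmosomal genes such as PKP2, was higher as a group. Of 20 tested members, 10 rose, 3 fell and 7 did not pass (12 rose and 3 fell adjusted over the list alone). The median was 0.41 log2 units, with an adjusted p of 0.0038 in camera and an adjusted p = 0.72 with an estimated correlation. The adjusted p in fry was 0.13. CDH1, which encodes E-cadherin, the main membrane partner of beta-catenin, rose by 2.27 log2 units (SE 0.19). CTNNAL1 rose by 1.26 (SE 0.09) and PKP2, which encodes the desmosomal protein plakophilin 2, by 1.26 (SE 0.12). NECTIN3, a nectin adhesion molecule, fell by 2.06 (SE 0.09).

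Intestinal crypt stem cell markers were lower as a group. Of 14 tested members, 8 fell, 2 rose and 4 did not pass (9 fell and 2 rose adjusted over the list alone). The median was -0.52 log2 units, with an adjusted p of 0.0073 in camera and an adjusted p = 0.70 with an estimated correlation. Without a level filter the median was -0.135. The falls included RNF43, AXIN2 and SOX9. These are also on the Wnt target list, as are many others of the 23 fixed crypt markers, among them CDCA7, ZNRF3, LGR5 and ASCL2. The lists are thus not independent, and this shift is in part that of the Wnt target list. The stem cell markers LGR5 and ASCL2 lay below the level filter and were not tested. ALCAM, a cell adhesion molecule, rose by 2.36 (SE 0.08). Neither list of markers of differentiated intestinal cells passed camera. Among 11 tested absorptive markers 3 rose, none fell and 8 did not pass, with a median of 0.05 log2 units and an adjusted p of 0.29 in camera, and the same 3 rose adjusted over the list alone. These 3 were DPP4, the magnesium channel gene TRPM6, which rose by 0.52 (SE 0.07), and the carbonic anhydrase gene CA2, which rose by 0.38 (SE 0.08). Among 17 tested goblet, Paneth and enteroendocrine markers 1 fell, none rose and 16 did not pass, with a median of -0.02 log2 units and an adjusted p of 0.87 in camera. That gene was SCG2, which encodes a granin, and it fell by 1.15 (SE 0.26), but none passed adjusted over the list alone.

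Cell cycle genes fell almost throughout. Of 46 tested G1/S and DNA replication genes, 44 fell, none rose and 2 did not pass, and of 49 tested G2/M and mitosis genes, 45 fell, 1 rose and 3 did not pass. Adjusted over each list alone, 44 and 46 genes fell. The medians were -0.83 and -0.90 log2 units. Both lists had an adjusted p of 3.23e-19 in camera. With an estimated correlation, they had an adjusted p = 0.46 and an adjusted p = 0.47. In the first list, the helicase gene BRIP1 fell by 2.08 (SE 0.20), and CCNE2, which encodes cyclin E2, fell by 2.06 (SE 0.23). The cohesion factor gene DSCC1 fell by 1.86 (SE 0.15), and DTL, which helps degrade a replication licensing factor, fell by 1.69 (SE 0.11). In the second, the kinetochore gene CENPF fell by 1.99 (SE 0.22), and HMMR fell by 1.72 (SE 0.12). CCNB1, which encodes cyclin B1, fell by 1.69 (SE 0.08), and the spindle checkpoint gene MAD2L1 fell by 1.68 (SE 0.10). The member that rose, named after its value was seen, was the phosphatase gene CDC25B at 0.99 (SE 0.09). Replication-dependent histone genes were also lower, with 14 of 19 tested members falling, 1 rising and 4 not passing (15 fell and 1 rose adjusted over the list alone). Their median was -0.78 log2 units, with an adjusted p of 3.00e-06 in camera and an adjusted p = 0.46 with an estimated correlation. H2AC21, H2BC14 and H1-4 had log2 fold changes of -2.36 (SE 0.11), -2.14 (SE 0.28) and -1.94 (SE 0.12), and H2AC6 rose by 1.90 (SE 0.28). These genes have near-identical copies whose signals an array may mix, and only 24 of the 53 listed histone genes had a cluster with 1 symbol, so their values are uncertain.

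MYC target and ribosome biogenesis genes shifted down by a small amount. Of 42 tested members, 14 fell, 2 rose and 26 did not pass, with the same counts adjusted over the list alone. The median was -0.17 log2 units, with an adjusted p of 0.0037 in camera and an adjusted p = 0.47 with an estimated correlation. RRP1B, a nucleolar protein gene, fell by 1.77 (SE 0.10), the RNA helicase gene DDX21 fell by 1.29 (SE 0.12) and FBL, which encodes the rRNA methyltransferase fibrillarin, fell by 0.97 (SE 0.09). TFRC, which encodes the transferrin receptor, rose by 1.22 (SE 0.10).

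Targets of p53 did not pass the list test. Of 33 tested members, 8 fell, 4 rose and 21 did not pass (9 fell and 4 rose adjusted over the list alone), with a median of -0.22 log2 units and an adjusted p of 0.16 in camera. The list held genes that moved strongly in opposite directions, with PMAIP1 and KITLG named above. The stress cytokine gene GDF15 fell by 1.62 (SE 0.12) and TP53INP1 by 1.48 (SE 0.12).

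Interferon-stimulated genes were higher as a group. Of 36 tested members, 20 rose, none fell and 16 did not pass (21 rose and 1 fell adjusted over the list alone). The median was 0.41 log2 units, with an adjusted p of 2.94e-08 in camera and an adjusted p = 0.46 with an estimated correlation. Without a level filter the median was 0.225, and among genes above the 50th percentile it was 0.79. SAMD9, an antiviral gene, rose by 2.32 (SE 0.24), and IFIH1, which encodes the double-stranded RNA sensor MDA5, rose by 2.12 (SE 0.16). DTX3L and PARP9, which encode an antiviral ubiquitin ligase complex, rose by 1.66 (SE 0.08) and 1.59 (SE 0.15).

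Targets of the Hippo pathway effectors YAP and TAZ were higher as a group. Of 23 tested members, 12 rose, 2 fell and 9 did not pass (13 rose and 3 fell adjusted over the list alone). The median was 0.30 log2 units, with an adjusted p of 0.0038 in camera and an adjusted p = 0.46 with an estimated correlation. The receptor tyrosine kinase gene AXL rose by 2.62 (SE 0.11), the ecto-nucleotidase gene NT5E by 2.44 (SE 0.38), CRIM1 by 2.34 (SE 0.08) and THBS1, which encodes thrombospondin 1, by 1.90 (SE 0.15).

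Genes of hypoxia and glycolysis, of lipid synthesis and of the epithelial-mesenchymal transition also passed camera. The hypoxia and glycolysis list had 8 members that rose, 2 that fell and 28 that did not pass, a median of 0.27 log2 units and an adjusted p of 0.0038, and an adjusted p = 0.74 with an estimated correlation. SLC2A1, which encodes a glucose transporter, fell by 2.66 (SE 0.23), while ERO1A, P4HA1 and BNIP3 rose by 1.56 (SE 0.19), 1.39 (SE 0.37) and 1.37 (SE 0.36). P4HA1 did not pass in limma after another quantile normalization (adjusted p 0.052) or without a level filter (adjusted p 0.056). Without control replicate 1 the BNIP3 log2 fold change was 0.855. The cholesterol and fatty acid list had 10 members that rose, 3 that fell and 15 that did not pass, a median of 0.19 log2 units and an adjusted p of 0.023, and an adjusted p = 0.74 with an estimated correlation. ELOVL6, a fatty acid elongase gene, rose by 2.54 (SE 0.09) and HMGCS1, of the mevalonate pathway, by 2.13 (SE 0.12), while SQLE and TMEM97 had log2 fold changes of -1.14 (SE 0.19) and -1.14 (SE 0.08). The transition list mixes epithelial and mesenchymal markers. It had 8 members that rose, 3 that fell and 13 that did not pass, a median of 0.13 log2 units and an adjusted p of 0.040, and an adjusted p = 0.72 with an estimated correlation. Besides CDH1, its largest changes were rises of the integrin genes ITGA5 and ITGAV by 1.71 (SE 0.16) and 1.45 (SE 0.12) and of the urokinase gene PLAU by 1.48 (SE 0.14). Adjusted over each list alone, 8, 10 and 10 members of the hypoxia, lipid and transition lists rose and 2, 3 and 3 fell. Each of these 3 calls was lost without control replicate 1, with adjusted p-values of 0.21, 0.21 and 0.27 in camera, and without CTNNB1 siRNA replicate 2, with 0.13, 0.19 and 0.15. Their medians were 0.2125, 0.165 and 0.025 in the first case and 0.20, 0.105 and 0.1525 in the second. In fry they had adjusted p-values of 0.48, 0.13 and 0.13. The transition list also missed the threshold on ranks, with 0.068, and without a level filter, with 0.060 and a median of 0.0275. Among genes above the 50th percentile it passed, with 0.014 and a median of 0.305, and without control replicate 2 its median was 0.2625.

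**Figure D3:**
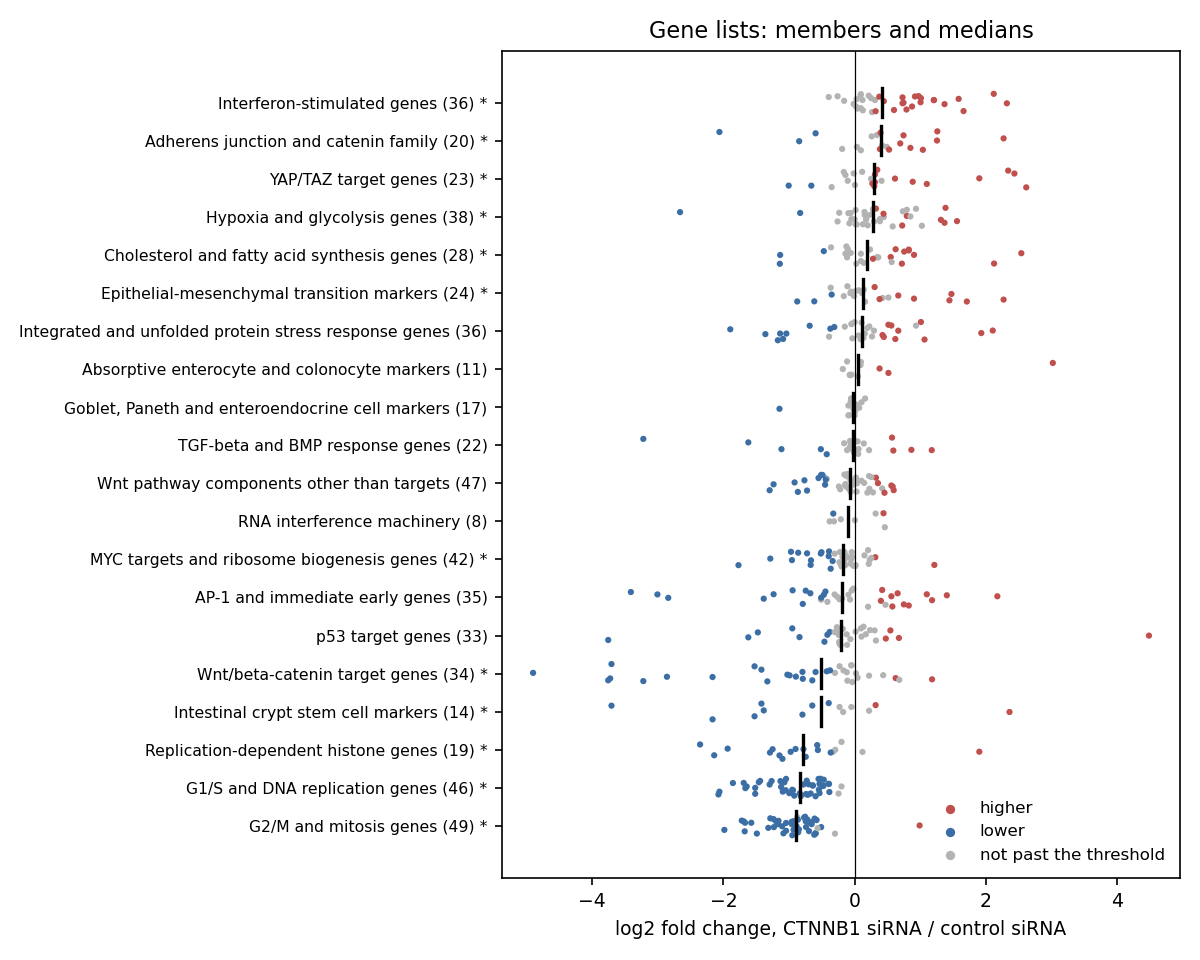
Log2 fold change after CTNNB1 siRNA (horizontal axis) of each tested member of 20 gene lists, with the number tested in brackets. Points are genes (red higher, blue lower, grey not past the threshold), black bars are list medians, and a star marks the 12 lists past an adjusted p of 0.05 in camera.

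The remaining lists did not pass camera. Medians of lists that did not pass moved with single arrays, to -0.12 for p53 targets without CTNNB1 siRNA replicate 1, to -0.075 for AP-1 genes without control replicate 2 and, for stress genes, to 0.0625 without control replicate 1 and 0.045 without CTNNB1 siRNA replicate 2. The median of Wnt components was -0.1025 without CTNNB1 siRNA replicate 2 and -0.115 among genes above the 50th percentile. The median of absorptive markers was 0.08 without CTNNB1 siRNA replicate 1, 0.025 without control replicate 2 and -0.005 without a level filter. Goblet, Paneth and enteroendocrine markers had medians of 0.005 and -0.0575 without control replicates 1 and 2, and of -0.085 and 0.025 without CTNNB1 siRNA replicates 1 and 2. Their median was -0.01125 after another quantile normalization and -0.035 without a level filter. TGF-beta and BMP response genes had medians of -0.005 without control replicate 2 and 0.0025 without CTNNB1 siRNA replicate 2. Their median was -0.0125 after another quantile normalization, -0.01 without a level filter and -0.05 among genes above the 50th percentile. Stress response genes split, with 10 members higher, 9 lower and 17 not passing (13 and 10 adjusted over the list alone). The median was 0.11 log2 units and the adjusted p was 0.49 in camera, while the direction in fry was down. The ER co-chaperone gene DNAJC3 rose by 2.11 (SE 0.16) and the cystine transporter gene SLC7A11 by 1.93 (SE 0.20). MTHFD2, of mitochondrial one-carbon metabolism, fell by 1.90 (SE 0.10) and the amino acid transporter gene SLC7A5 by 1.36 (SE 0.08). AP-1 and immediate early genes also split, with 11 higher, 12 lower and 12 not passing (11 and 14 adjusted over the list alone), a median of -0.19 log2 units and an adjusted p of 0.49 in camera. Against the falls of DUSP6, NR4A2 and EGR1, the mRNA decay factor gene ZFP36 rose by 2.18 (SE 0.21). Among TGF-beta and BMP response genes 4 were higher, 5 lower and 13 not passing, with the same counts adjusted over the list alone, a median of -0.03 log2 units and an adjusted p of 0.83 in camera. ID1, a BMP target, rose by 1.18 (SE 0.16), and TGIF1 fell by 1.12 (SE 0.08). Genes of the RNA interference machinery had 1 member higher, TNRC6C at 0.44 (SE 0.11), 1 lower, XPO5 at -0.33 (SE 0.09), and 6 not passing (3 and 3 adjusted over the list alone). XPO5 did not pass in limma with trend and robust settings (adjusted p 0.061) or without a level filter (adjusted p 0.060). The median of the list was -0.10 log2 units, its mean -0.0006 and the adjusted p in camera 0.93. Markers of other cell types had too few members above the level filter for a list test. None of 7 fibroblast markers passed, and of 6 leukocyte and endothelial markers only CD68, a lysosomal protein gene, rose, by 1.64 (SE 0.08), with the same result adjusted over the list alone.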

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

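The search among unnamed transcript clusters was not among the comparisons fixed before the data were examined. Clusters without a gene name in the annotation table are outside the comparisons above, and a smaller share of them changed than the 30.3% of tested named genes. Of 21417 unnamed clusters above the level filter, 629 were higher and 595 lower at an adjusted p under 0.05 in limma, fitted together with 1155 clusters that carry several symbols. Of these called clusters, 351 rose at least 2-fold over the control arrays and 282 fell by that size. The largest rise was that of cluster TC18000741.hg.1, from 8.39 to 13.66 log2 units, a change of 5.27 (SE 0.15, adjusted p 0.00082 in limma). The largest fall was that of cluster TC06002615.hg.1, from 14.14 to 8.12 log2 units, a change of -6.02 (SE 0.20, adjusted p 0.0011 in limma). Both exceeded the largest change in the same direction among called protein-coding genes whose groups did not overlap, 4.49 for PMAIP1 and -4.90 for SOX4. Other clusters with a name were not compared with them. The clusters of PMAIP1 (TC18000213.hg.1, chromosome 18) and SOX4 (TC06000135.hg.1, chromosome 6) have names that begin like those of the unnamed riser and faller. Whether the unnamed clusters belong to the same loci as these genes was not examined, so they may not be separate changes. No explanation was tested. Groups of 2 arrays were too small to look for a single deviating array by a test of gaps.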

How the results depend on the processing

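No called list and no called named gene reversed its direction under any of the alternatives run. For the named genes this was largely fixed in advance. Genes whose groups do not overlap cannot change sign when an array is left out, and the replicate block and the eBayes settings leave a fold change as it was. The number of called genes stayed between 3898 and 5976 under the replicate block, trend and robust eBayes, quantile normalization, median centring, both filters, the mean of clusters, each cluster on its own and an adjusted p under 0.10. A fold of at least 1.5 in addition left 2455 genes (1168 higher, 1287 lower) and a fold of at least 2 left 894 (451 and 443), by construction. Leaving out any 1 array gave 0 called genes in limma, higher and lower alike, with smallest adjusted p-values from 0.054 to 0.076 and 4739 to 4939 genes at an unadjusted p under 0.05. The lone array of a group is then assumed to vary like the other group, and 1 residual degree of freedom is left. All of the 4744 to 4754 called genes still tested kept their sign in those fits, which share 3 of the 4 arrays with the full one. CTNNB1 then changed by -3.63 to -3.48. With an estimated correlation 0 of the 12 lists passed, at unmoved medians of -0.51 (Wnt targets), 0.41 (adherens junctions), -0.52 (crypt stem cells), -0.83 (G1/S), -0.90 (G2/M), -0.17 (MYC targets), 0.41 (interferon), 0.19 (lipid synthesis), 0.27 (hypoxia), 0.30 (YAP/TAZ), 0.13 (transition markers) and -0.78 (histones). The correlation was estimated from 2 residual degrees of freedom. The YAP/TAZ and histone lists lost their call although their estimates lay under the preset 0.01. By fry the adherens junction, lipid synthesis, hypoxia and transition lists did not pass (adjusted p 0.13, 0.13, 0.48 and 0.13), and the absorptive marker and TGF-beta lists did (0.043 and 0.043). The transition list, at 0.13, also missed the threshold under the replicate block (adjusted p 0.055) and on ranks (0.068), and without a level filter its median was 0.0275 (0.060). With arrays left out, medians ranged from 0.11 to 0.27 for lipid synthesis, from 0.20 to 0.34 for hypoxia and from 0.025 to 0.26 for transition markers, and the other 9 called lists kept their call. The cause of these losses was not tested. Same-numbered arrays deviated together (r = 0.27 across genes), but 2 pairs with no shared culture in the labels do not establish a pairing. The replicate block gave 3898 genes, of which 3707 were also called without it, and it changed no list call other than that of the transition markers. Among 104 named genes besides CTNNB1, the alternatives that kept all arrays moved 7 of 715 values across the threshold, 5 out and 2 in, all of P4HA1, XPO5 and TNRC6A.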

Other observations

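The tests of the Wnt targets among the largest falls, of the NRF2 targets, of the stress list's parts and of the strongly inducible interferon genes were chosen after the results were seen, and the genes named below were chosen after their values were seen. In a list of 34 known targets of NRF2, the transcription factor of the oxidative stress response, 24 of 29 tested genes rose, 1 fell and 4 did not pass, with a median of 1.31 log2 units. HMOX1, which encodes heme oxygenase 1, rose by 2.97 log2 units (SE 0.08), the thioredoxin reductase gene TXNRD1 by 1.81 (SE 0.08), the glutathione reductase gene GSR by 1.31 (SE 0.11) and GCLC by 1.03 (SE 0.08). NQO1, a widely used marker of the pathway, was at 13.94 and 14.05 log2 units in the 2 groups and did not pass (0.11, SE 0.11, adjusted p 0.56 in limma). TXN, which encodes thioredoxin, did not pass either (0.17, SE 0.09, adjusted p 0.23 in limma). The PGD gene of the pentose phosphate pathway fell by 0.39 (SE 0.09).

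The stress response list, which did not pass camera as a whole, was divided into 2 parts after its members were seen to go both ways. Of 14 tested endoplasmic reticulum chaperone and quality control genes, 7 rose and none fell, including CALR at 1.07 (SE 0.12), HERPUD1 at 1.01 (SE 0.14) and HSPA5 at 0.67 (SE 0.16). Of 22 tested genes of amino acid supply and the ATF4 arm, 9 fell and 3 rose. ATF4 fell by 1.17 (SE 0.12), and the asparagine synthetase gene ASNS fell by 1.09 (SE 0.08). The serine synthesis genes PSAT1 and PHGDH had log2 fold changes of -1.14 (SE 0.12) and -1.04 (SE 0.10). The median of the amino acid part lay 0.46 log2 units under that of the chaperones (difference -0.46). Because the parts were drawn from these values, the difference describes the list and bears out no division of it.

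Of the 12 named genes with the largest falls besides CTNNB1, 6 were on the Wnt/beta-catenin target list, namely SOX4, KITLG, JAG1, RNF43, BMP4 and FGF9. The list supplied 34 of 12768 tested protein-coding genes, and Fisher's exact test gave a 1-sided p of 2.04e-13. None of the 12 largest rises was on it. This p treats genes as independent, which they are not. The list was fixed beforehand, but the test was chosen after these falls were seen. Its p therefore describes the overlap and is no separate evidence beside the list test above.

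A higher activity of NRF2 is an untested hypothesis for the rise of its listed targets. Without the genes among the 12 largest rises, 21 of 26 tested targets rose, with a median of 1.01 log2 units and p = 1.70e-12 in camera (p = 0.039 with an estimated correlation). The list was chosen after such genes were seen to rise, and HMOX1, TXNRD1, GSR and GCLC were still in it, so this p is no evidence for the hypothesis. The mRNAs of NRF2 itself (NFE2L2, -0.07, SE 0.09) and of its inhibitor KEAP1 (0.06, SE 0.08) did not pass the test. Protein levels were not measured. An effect of the siRNA sequence on other transcripts stays open for this and for every other change, because 1 CTNNB1 siRNA condition was compared with 1 control condition.

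The fall of the cell cycle lists was set against 2 technical explanations. An intensity-dependent shift of the arrays would lower random lists of the same level as much, but among 10000 random lists matched on mean level none had a median as low as either list (percentile 0). The lowest random medians were -0.32 for G1/S and -0.41 for G2/M, against -0.83 and -0.90. If 1 deviant array carried the fall, a fit without it would bring a median near 0, but the median nearest to 0 over the 4 such fits was -0.78. A lower share of dividing cells after CTNNB1 siRNA, a direct action on these genes and an off-target action of the siRNA stay open, and no measurement of proliferation was used here.

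The rise of the interferon list was set against an intensity-dependent shift as well, and its median of 0.41 lay above all of 10000 matched random lists (percentile 100, highest 0.15). Another candidate explanation is interferon secreted by cells that sense the siRNA, in which case the most inducible genes should lead. The 8 tested strongly inducible members had a median lower by 0.23 than the other 28 (difference -0.23, permutation p = 0.66), so the test decides nothing. Control levels of these 8 were low, from 4.27 (IFIT1) to 5.445 log2 units (IFIT3), which may limit how far their changes can be measured. IFIT2, IFIT1, IFI44 and IFIT3 rose, by 0.375 to 0.975 log2 units. OASL (0.215), OAS1 (0.125), ISG15 (0.12) and MX1 (0.095) did not pass. IFNB1 and IFNA1 lay below the level filter in all 4 arrays, and IFNL1 did not pass (-0.06, SE 0.10). Of the RNA sensor genes looked at, TLR3 rose by 1.96 (SE 0.08) and EIF2AK2 by 0.93 (SE 0.08), as did IFIH1 above, while RIGI did not pass (0.09, SE 0.11, adjusted p 0.64 in limma). Both groups received an siRNA, and whether their sequences differ in immune stimulation cannot be told apart from an effect of lower CTNNB1 in this design.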
